A study of Mus musculus with 2 samples.

How the data were processed

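RNA was measured in 2 libraries of mouse ear skin, 1 labelled wild type (WT) and 1 labelled KAT8 conditional knockout (KAT8 cKO). KAT8, also called MOF, is a histone acetyltransferase that acts within the MSL and NSL complexes. Per the labels' protocols, ears in both groups had received 30 mg of a 5% imiquimod cream daily for 3 days and were collected on day 4. Imiquimod is an agonist of the receptor TLR7, and its repeated application to mouse skin produces a psoriasis-like inflammation. The cell type or promoter that drives the knockout is not given in the sources used here, nor are the sex, age, strain or number of animals behind a library. Per the labels' protocols, polyadenylated RNA was selected from total RNA, fragmented and made into libraries with a kit for Illumina sequencing.

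The deposited table holds raw counts per Ensembl gene, whole numbers with no normalization, for 34745 genes. HISAT2, StringTie 1.3.0, edgeR and the mouse build mm10 are named per the submitters' processing notes, without saying which step each did. The tool that made the counts, the gene annotation release and whether strand was used in counting are not given in the sources used here. Without strand, reads in exons shared with another gene, on either strand, cannot be told apart, and reads from near-identical copies such as the Hba, Sprr2, Serpinb3 and Stfa genes may be split between them. Of the 15240 genes measured, 31.0% had an exon that overlapped an exon of another gene in the table.

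Gene identifiers were paired with symbols from GENCODE mouse release M21, which is on GRCm38, the assembly that mm10 names. A symbol was found for 34267 genes. The other 478 genes held 0.103% of the counts in the WT library and 0.0968% in the cKO library and stayed in the library totals. Coordinates are from the same release, counted from 1.

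The analysis fixed before the data were examined expected FPKM values and named the alternative used here for counts. Counts were divided by the library total times a trimmed mean of M values (TMM) factor from edgeR 4.0.16 (R 4.3.3), giving scaled counts per fixed total (CPM). The factors were 0.946 for the WT library and 1.06 for the cKO library. The log2 ratio of a gene is log2 of (cKO CPM + 1) over (WT CPM + 1), which understates the difference of genes with low counts. A gene was measured if it had at least 1 CPM in either library, and it was counted as higher or lower if its log2 ratio was at least 1 in size, a 2-fold difference. Folds in the text are plain ratios of CPM with exact (Clopper-Pearson) 95% intervals from the counts of that gene. A gene with 0 counts in one library was set to a floor of 3 counts in that library for a lower bound. These intervals and floors cover counting error only. Reads without molecular identifiers are not independent molecules.

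With 1 library per genotype there are no replicates, so no test across genes was run, no p-value is given, and no difference could be set against the spread between animals. Differences therefore describe these 2 libraries and not the genotypes. DESeq2 and edgeR were not used for testing for the same reason. At these totals, 1 count was 0.0868 CPM in the WT library and 0.0689 CPM in the cKO library, and the floor of 3 counts was 0.260 and 0.207 CPM.

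Gene lists (39 lists of cell type markers and pathways, 689 entries, of which 3 found no gene) were fixed before the data were examined. Older symbols were matched through RefSeq synonyms, so that IL-36 genes appear as Il1f6, Il1f8 and Il1f9. The median log2 ratio of a list's measured members was ranked among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5. Chance would put 1.95 of 39 lists outside this range if the genes of a list varied independently, which co-regulated genes do not. A further 6 lists were written after the data had been seen and are described only under the closing observations. Genes were named in the text by a rule fixed in advance. It took Kat8, up to 4 members of each list with the largest log2 ratios of 1 or more in size (or, where fewer than 2 reached this, the 2 members with the highest mean level), and the 10 highest and 10 lowest ratios among genes with at least 5 CPM in either library and an established symbol. The rule named 140 genes, of which some are not reported here. Other genes named were chosen after their values were seen, and the text says so.

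The calculations were tested on simulated data, Poisson counts for all 34745 genes drawn from the real means and totals with 200 genes changed. The 200 changed genes were drawn only from genes with a mean of at least 5 CPM. Among these, the rule of size recovered 94.0% of genes changed by 2.5-fold and 100% of those changed by 4-fold or 8-fold. Recovery of genes at lower levels was not simulated. None of 14803 unchanged genes passed it, a figure for counting error without any variation between animals. The alternatives tried were a pseudocount of 0.1, no filter or a filter of 5 CPM, a limit of 2 on the log2 ratio, centring on the median, a total without the 50 highest genes, and random lists not matched on level. Plain CPM, DESeq2 1.42.0 size factors and leaving out groups of genes were added after the data had been seen. The planned rescaling by a trimmed mean of log ratios is the TMM scaling itself. Leaving out a replicate was not possible.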

Results

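Ear skin from imiquimod-treated mice was profiled by RNA-seq in 2 libraries, 1 labelled WT and 1 labelled KAT8 cKO. The libraries held 12179608 and 13727524 counts on genes, with 19131 and 19143 genes detected by at least 1 count. Mitochondrially encoded transcripts took 7.61% of the counts in the WT library and 6.27% in the cKO library. The 50 most abundant genes took 19.1% and 15.8%. No untreated skin was analysed here, so the values compare 2 treated specimens and do not give the response to imiquimod. There were no replicates.

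The targeted gene was not lower in the library labelled KAT8 cKO. Kat8 (ENSMUSG00000030801, chromosome 7 from 127912516 to 127925837 on the plus strand, GRCm38) had 219 counts in the library labelled WT and 351 in the library labelled KAT8 cKO, a ratio of CPM of 1.27 (95% interval 1.07 to 1.51). The table gives 1 value for the whole gene, which also covers cells outside a conditional knockout and exons outside a deleted part. An exon of Kat8 overlaps one of Prss8, so the value checks the label only weakly. None of the 12 measured KAT8 complex genes differed by 2-fold, and their median log2 ratio was 0.19, at percentile 87.2. The 2 most abundant, Hcfc1 and Ogt, had log2 ratios of 0.85 and -0.63. Because Kat8 was not lower and does not settle the label, the libraries are named below by their labels.

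The libraries also differed in sex-linked transcripts. Xist (chromosome X from 103460366 to 103483254), the RNA that silences an X chromosome in female cells, had 11891 counts in the library labelled WT and 6 in the library labelled KAT8 cKO. The Y-linked genes went the other way. Eif2s3y had 0 and 838 counts (at least 222-fold higher in the library labelled KAT8 cKO), Kdm5d 0 and 305 (at least 80.7-fold) and Ddx3y 5 and 635 (101-fold, interval 43.0 to 312). The median log2 ratio of the 5 measured sex-linked genes was 4.46, or 5.78 with genes at 0 counts set to their bound. Sex-linked transcripts and genotype labels therefore coincide in every comparison that follows.

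Comparing the 2 libraries, 695 genes were at least 2-fold higher and 1315 at least 2-fold lower in the library labelled KAT8 cKO, out of 15240 measured. Apart from the sex-linked genes, the sebaceous list had the highest median (2.35), and the adipocyte and red cell lists lay lowest (-2.58 and -2.47). The red cell median was -2.84 with a gene at 0 counts set to its bound. With no filter it was -1.40, above the muscle and neutrophil medians (-2.07 and -2.05). The largest ratios upward outside the Y chromosome were those of Pcdhga2, Acoxl, Far2, Fa2h, Pcdhgc4, Elovl3 and Elovl6. Fa2h, a fatty acid 2-hydroxylase, went from 32.7 to 815 CPM (24.9-fold, interval 22.5 to 27.7). Elovl6, a fatty acid elongase, went from 62.6 to 1089 CPM (17.4-fold), and Acoxl from 2.08 to 88.3 CPM (42.4-fold, interval 28.4 to 66.4). Downward, after Xist, the largest were those of Cyp2e1, Thrsp, Pck1, Cfd, Pcdhgb2, Mybpc2, Ngp, Nos2 and Rptn. Cyp2e1, a cytochrome P450, went from 3983 to 29 counts (173-fold lower, interval 120 to 259). Pck1, an enzyme of gluconeogenesis, was 42.1-fold lower, and Thrsp, a regulator of fat synthesis, 46.4-fold lower. Cfd, also among the lowest genes, is a member of the adipocyte list, whose median was -2.58 in the same library. Nos2, the inducible nitric oxide synthase (chromosome 11 from 78920787 to 78960254), went from 512 to 27.8 CPM (18.4-fold lower, interval 16.7 to 20.4). The protocadherin genes share exons. Pcdhga2 and Pcdhgc4 were 168-fold and 72.1-fold higher and Pcdhgb2 33.7-fold lower, but the total over the 22 genes of this cluster differed by 1.23-fold (2539 and 3919 counts), so single members are uncertain. The median log2 ratio of measured genes was 0.01. With plain CPM it was 0.16, and the counts were 964 higher and 1056 lower.

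**Figure D1:**
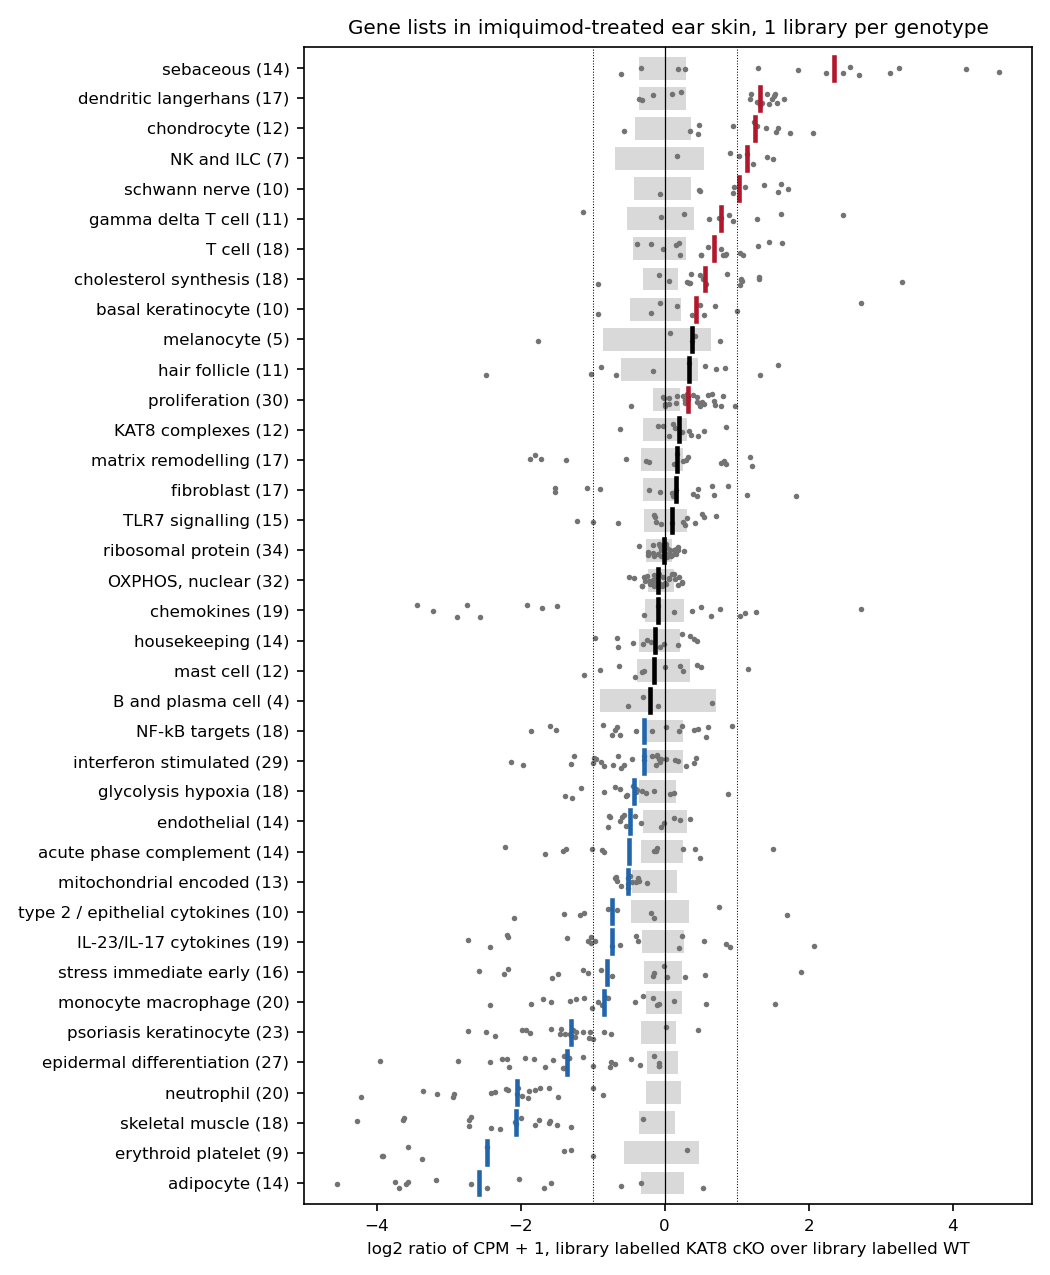
Log2 ratios (library labelled KAT8 cKO over library labelled WT, horizontal axis) of the measured members of 38 gene lists, with the number measured in parentheses; each dot is a gene, the thick line is the list median (red above, blue below and black within the random range), the grey band is the central 95% of 10000 random lists matched on level, and dotted lines mark 2-fold. The sebaceous median of 2.35 lies farthest to the right, and the adipocyte and red cell medians of -2.58 and -2.47 lie far to the left.

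The lists of IL-23/IL-17 cytokines and of psoriatic keratinocyte genes stood below the random range in the library labelled KAT8 cKO, while Il17f was higher. The lists of neutrophils (median -2.05), monocytes and macrophages (-0.85), muscle (-2.07) and adipocytes (-2.58) were lower in the same library. So was the immediate early list, which also holds heat shock genes (-0.80, or -0.16 without genes that share exons). Myeloid cells also express Il1b and S100a8. Of 19 measured genes of the IL-23/IL-17 list, 8 were at least 2-fold lower and 1 higher (median log2 ratio -0.74, below all 10000 random lists, or -0.42 at percentile 0.17 with no filter). The lower ones were led by the IL-1 and IL-36 family. Il1b went from 1238 to 271 CPM (4.57-fold lower, interval 4.41 to 4.73), Il1a from 64.3 to 11.2 CPM (5.76-fold), Il1f6, which encodes IL-36 alpha, from 907 to 159 counts (7.19-fold) and Il1f8 from 353 to 87 counts (5.11-fold). The single higher gene, Il17f, named after its value was seen, went from 20 to 153 counts (6.07-fold). Il17a, likewise chosen afterwards, had 14 and 46 counts, a plain ratio of 2.61 (interval 1.41 to 5.14) and, with the pseudocount of 1, a log2 ratio of 0.91. In the psoriatic keratinocyte list 18 of 23 genes were lower and none higher (median -1.30, below all random lists). Sprr1b, a cornified envelope precursor, was 5.63-fold lower, the antimicrobial peptide gene Defb4 6.61-fold lower (215 and 41 counts) and the protease inhibitor gene Slpi 3.99-fold lower. The wound keratin gene Krt16 and the alarmin gene S100a8, chosen after their values were seen, went from 4409 to 1474 CPM and from 5844 to 2230 CPM. Il1f6 stands in both lists. The late epidermal differentiation list was lower in the same library as well (median -1.36), and the basal keratinocyte list was higher (0.44).

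Chemokines split in both directions, in a library where the neutrophil, monocyte, muscle and adipocyte lists were lower (medians -2.05, -0.85, -2.07 and -2.58). Of 19 measured, 8 were lower and 4 higher, with a median of -0.10 at percentile 22.4 that lay at 0.06 with plain CPM and at 0.01 without the 50 highest genes. The B cell attractant Cxcl13 was 11.3-fold lower, the monocyte and neutrophil attractants Ccl3, Ccl4 and Cxcl2 were 9.80-fold, 7.04-fold and 7.44-fold lower, with Cxcl2 going from 1591 to 214 CPM. Among the 4 higher genes, named after their values were seen, Ccl22 went from 2.52 to 22.4 CPM and Ccl20 from 29.6 to 65.5 CPM, beside Ccl7 and Cxcl14. Interferon-stimulated genes had 4 lower and 25 within 2-fold (median -0.29, percentile 1.87), and the lower ones included Gbp2 (4.66-fold), Ifi27l2a (3.97-fold) and Igtp (2.67-fold). In the NF-kB target list 3 of 18 were lower, namely Ptgs2, Tnfaip3 and Vcam1 by 3.66-fold, 3.09-fold and 3.17-fold (median -0.28, percentile 1.82). Acute phase and complement genes had 5 lower and 1 higher of 14 (median -0.50, percentile 0.35). Saa3 and Hp were 3.18-fold and 2.67-fold lower and Ptx3 2.91-fold higher. Of 10 measured genes of the type 2 and epithelial cytokine list 4 were lower and 1 higher (median -0.73, percentile 0.37). Arg1 and Chil3, which do not encode cytokines or their receptors, were 4.45-fold and 2.64-fold lower. The cytokine gene Il33 was 2.27-fold lower and the decoy receptor gene Il13ra2 3.79-fold higher. TLR7 pathway genes did not stand apart (1 of 15 lower, median 0.11, percentile 71.4), and Nfkb1 and Myd88 had log2 ratios of 0.25 and -0.05. The NF-kB list lay within the range (percentile 3.23) against random lists not matched on level, the acute phase list with a filter of 5 CPM (percentile 20.3) and the type 2 list with no filter (percentile 8.49). The interferon median was -0.59 with a filter of 5 CPM, and the interferon and NF-kB medians were -0.14 and -0.13 with plain CPM.

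Leukocyte markers differed in direction. Neutrophil genes were lower in the library labelled KAT8 cKO, 18 of 20 by at least 2-fold and none higher, with a median of -2.05 below all random lists. Ngp, a granule protein gene (chromosome 9 from 110419747 to 110423012), went from 535 to 27.9 CPM (19.2-fold lower, interval 17.3 to 21.3). The collagenase gene Mmp8 went from 633 to 60.8 CPM (10.4-fold), Retnlg from 1574 to 174 CPM (9.03-fold) and Stfa2l1 from 109 to 13.4 CPM (8.17-fold). Haemoglobin genes, a sign of blood in the specimen, totalled 162 and 8.34 CPM. Monocyte and macrophage genes had 8 lower and 1 higher of 20 (median -0.85, below all random lists). Cd14, Cd163, Itgam and Ly6c2 were 5.39-fold, 3.70-fold, 3.27-fold and 3.10-fold lower, and Itgam and Cd14 are also expressed by neutrophils. The 1 higher gene, Apoe, named after its value was seen, was 2.90-fold higher and is not restricted to macrophages.

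The dendritic cell, T cell and natural killer lists stood above the random range in the same library, and the B cell list did not stand apart. The muscle and adipocyte lists were lower there (medians -2.07 and -2.58) and the cartilage and Schwann cell lists higher (1.26 and 1.04). Of 17 dendritic and Langerhans cell genes 12 were higher and none lower (median 1.32, above all random lists). The class II gene H2-Ab1 went from 56.9 to 166 CPM (2.91-fold, interval 2.67 to 3.18) and its activator Ciita from 3.30 to 11.6 CPM (3.53-fold). The migration receptor gene Ccr7 had 19 and 107 counts (4.47-fold) and Mgl2 20 and 99 (3.93-fold). T cell genes had 5 of 18 higher (median 0.69, percentile 99.98, or 1.17 with a filter of 5 CPM). Thy1, also expressed by fibroblasts, went from 86.7 to 215 CPM (2.48-fold), and the kinase genes Lck and Zap70 had 17 and 84 counts and 6 and 54 counts. Icos had 11 and 46. Of 11 gamma delta T cell genes 3 were higher and 1 lower (median 0.78, percentile 99.94, or 1.23 with a pseudocount of 0.1). Trdc, the delta chain constant gene, had 37 and 134 counts (2.87-fold, interval 1.98 to 4.26), Tcrg-C1 5 and 49 counts, 5830411N06Rik 8 and 122 counts and Zbtb16 261 and 142. Among 7 natural killer and innate lymphoid genes 5 were higher (median 1.14, percentile 99.93, or 0.72 with no filter). Gata3, also expressed in epidermis, was 2.74-fold higher. The cytotoxic granule genes Gzma, Nkg7 and Prf1 had 14 and 61, 11 and 48, and 2 and 34 counts, the last a ratio of 13.5 (interval 3.46 to 116). B and plasma cell genes were at percentile 31.6 (4 measured, none past 2-fold, median -0.20), with Ighm at a log2 ratio of -0.10 and Igkc at -0.51. Mast cell genes were at percentile 22.5 (median -0.14, or 0.22 with a filter of 5 CPM, 1 of 12 higher and 1 lower). They were Mcpt4, 2.28-fold higher, and Hpgds, 2.25-fold lower.

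**Figure D2:**
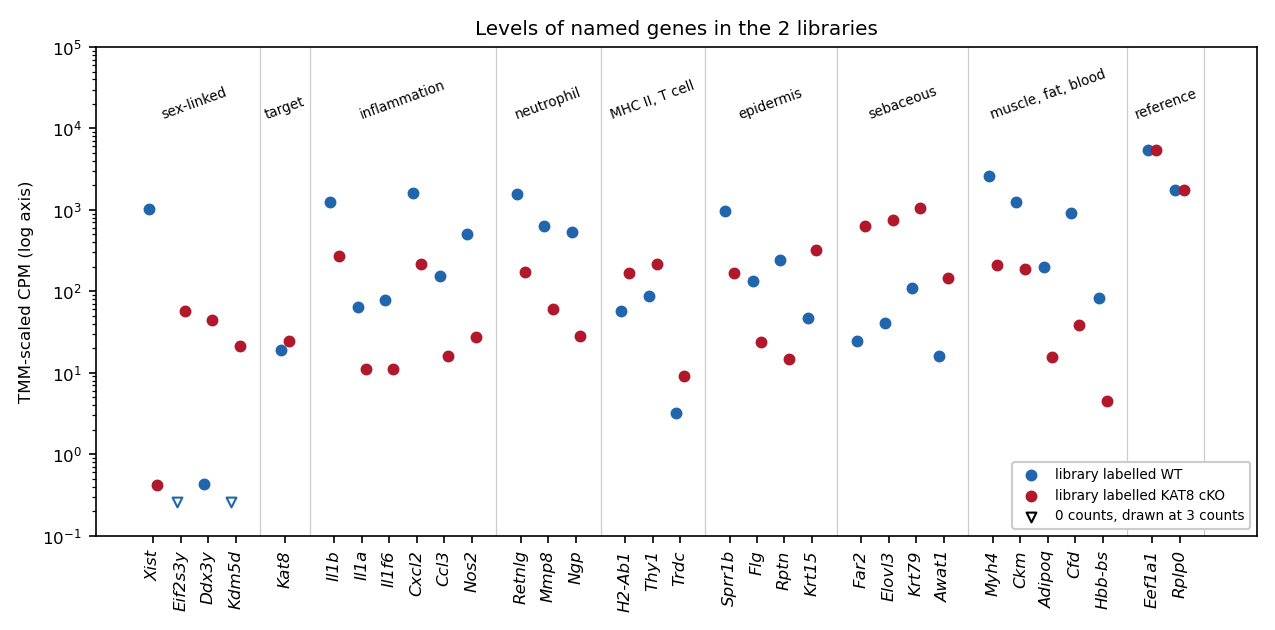
TMM-scaled CPM (log axis) of named genes in the library labelled WT (blue) and the library labelled KAT8 cKO (red), 1 value per library. Open triangles are genes with 0 counts drawn at the floor of 3 counts, and Il1b stands at 1238 and 271 CPM and Far2 at 24.6 and 638 CPM, while the reference gene Eef1a1 stands at 5452 and 5425 CPM.

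The list of late epidermal differentiation stood below the random range in the library labelled KAT8 cKO, while the basal and cell cycle lists stood above it. In the same library the muscle, adipocyte and neutrophil lists were lower (medians -2.07, -2.58 and -2.05) and the sebaceous list was higher (2.35). Of 27 measured differentiation genes 17 were at least 2-fold lower and none higher (median -1.36, below all random lists). Rptn, Hrnr and Flg, precursors of the cornified layer, were 16.4-fold, 7.48-fold and 5.55-fold lower, and the desmosomal cadherin gene Dsc1 4.91-fold lower. Rptn went from 244 to 14.8 CPM. Of 10 basal keratinocyte genes 2 were higher (median 0.44, percentile 99.93), Krt15 from 47.5 to 322 CPM (6.77-fold, interval 6.20 to 7.41) and Col17a1 from 533 to 1073 CPM (2.01-fold). None of 30 cell cycle genes differed by 2-fold, but 26 had ratios above 0 (median 0.32, percentile 99.92). Mki67 and Top2a had log2 ratios of 0.16 and 0.45. Hair shaft and root sheath genes were at low levels (11 of 26 measured) with 2 higher and 2 lower (median 0.34, percentile 93.8), and the median was -0.16 with a filter of 5 CPM. Lhx2 went from 24 to 119 counts and Lef1 from 7 to 44, Krt83 from 124 to 16 and Padi3 from 20 to 5.

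Sebaceous gland genes were the list with the highest median in the library labelled KAT8 cKO apart from the sex-linked genes. Of 14 measured, 10 were at least 2-fold higher and none lower (median 2.35, above all random lists). Far2, a fatty acyl-CoA reductase (chromosome 6 from 148047259 to 148182758), went from 24.6 to 638 CPM (26.0-fold, interval 23.1 to 29.4). The elongase gene Elovl3 (chromosome 19 from 46131897 to 46135694) went from 40.8 to 759 CPM (18.6-fold, interval 17.0 to 20.4). Krt79, a keratin of the gland duct, was 9.65-fold and the wax synthase gene Awat1 9.28-fold higher. Exons of Far2 and Elovl3 overlap those of other genes. Cholesterol synthesis genes were higher as well (7 of 18, none lower, median 0.56, above all random lists). Among them, Dhcr7 went from 69.8 to 174 CPM and Lss from 125 to 311 CPM. Y-linked transcripts (Eif2s3y 0 and 838 counts) and the cartilage and Schwann cell lists (medians 1.26 and 1.04) were higher in the same library, and the muscle and adipocyte lists were lower (-2.07 and -2.58).

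Markers of muscle, fat and blood in the specimen were far lower in the library labelled KAT8 cKO. Skeletal muscle genes were lower in 17 of 18 cases (median -2.07, below all random lists) and took 1.97% of the counts in the library labelled WT and 0.463% in the other. The fast myosin gene Myh4 went from 2632 to 211 CPM (12.5-fold lower, interval 12.0 to 13.0), and Actn3, Mybpc2 and Ckm were 12.6-fold, 20.8-fold and 6.64-fold lower. Adipocyte genes were lower in 11 of 14 cases (median -2.58, below all random lists), with Adipoq, which encodes adiponectin, going from 199 to 15.6 CPM (12.7-fold lower, interval 11.1 to 14.7). Cfd and Retn were 24.0-fold and 15.4-fold lower, and Cidec went from 2519 to 232 counts. Of 9 red cell and platelet genes 7 were lower (median -2.47, or -2.84 with Slc4a1, at 0 counts in one library, set to its bound and -1.40 with no filter). Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 were 18.3-fold, 40.6-fold, 17.5-fold and 17.5-fold lower, though reads of these near-identical pairs may be split.

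Other stromal lists differed less or went the other way. Cartilage genes were higher in 7 of 12 cases (median 1.26, above all random lists), led by Sox9 at 4.46-fold, which hair follicles also express, and by Cnmd, Col9a1 and Col9a3 at 3.90-fold, 4.04-fold and 3.16-fold. Schwann cell genes were higher in 5 of 10 cases (median 1.04, above all random lists), with Sox10, Ncmap and Prx 3.87-fold, 3.58-fold and 2.70-fold higher. Endothelial genes had a median of -0.48 (percentile 0.23) with none of 14 past 2-fold, and Pecam1 and Eng had log2 ratios of -0.33 and -0.05. Fibroblast genes were at percentile 94.2 (median 0.16, 2 higher and 3 lower of 17). Postn and Col1a1 were 3.54-fold and 2.21-fold higher, Mfap5 and Dpt 3.07-fold and 2.91-fold lower. Matrix remodelling genes were at percentile 92.6 (median 0.18, 2 higher and 4 lower of 17), the lower ones including Plaur (3.69-fold), Mmp9 (3.52-fold) and Mmp12 (4.67-fold). Melanocyte genes were at percentile 88.5 (5 measured, median 0.38), with Mitf 4.00-fold lower and Dct at a log2 ratio of 0.77.

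The immediate early list holds immediate early genes, which respond to handling as well as to inflammation, and heat shock genes. Its members were lower in 7 of 16 cases and higher in 1 (median -0.80, below all random lists). Fosb, Fos and Dusp1 were 7.04-fold, 4.78-fold and 4.57-fold lower and Egr2 3.97-fold higher. Glycolytic and hypoxia-inducible genes had 3 lower of 18 (median -0.42, percentile 0.97, or -0.26 with plain CPM), namely Bnip3, Slc16a3 and Vegfa by 2.64-fold, 2.44-fold and 2.25-fold. The muscle list, whose tissue is rich in glycolytic and mitochondrial transcripts, was lower in the same library (median -2.07), as was the neutrophil list (-2.05). All 13 mitochondrially encoded genes had ratios below 0 without reaching 2-fold (median -0.51, percentile 1.44), mt-Co1 at -0.40 and mt-Nd1 at -0.24. Nuclear genes of oxidative phosphorylation were at percentile 27.3 (median -0.10), with Atp5b at -0.02 and Atp5a1 at 0.24. Ribosomal protein genes were at percentile 76.2 (median -0.01), with Rpl4 at -0.05 and Rplp0 at -0.02. Reference genes were at percentile 28.1 (median -0.13), with Eef1a1 at -0.01 and Actb at -0.67. The signs of these 3 medians near 0 rest on the scaling, as they lay at 0.06, 0.15 and 0.03 with plain CPM. Without genes whose exons overlap another gene, the immediate early, glycolytic and mitochondrial lists lay within the random range at percentiles 16.8, 4.37 and 8.78. The immediate early median was then -0.16, while the glycolytic and mitochondrial medians were -0.40 and -0.46.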

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

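Plain CPM, DESeq2 size factors and leaving out groups of genes were chosen after the data had been seen. The limit of 2 on the log2 ratio moved the counts most, to 119 genes higher and 246 lower, by its own construction. No named gene past 2-fold and no list that stood apart changed direction under the alternatives run for it. Plain CPM without TMM moved the share of higher genes among those past 2-fold from 34.6% to 47.7% and the median of all measured genes to 0.16. A total without the 50 highest genes moved that share to 42.8% (911 higher, 1216 lower) and the median to 0.10. A pseudocount of 0.1 gave 1012 and 1722 genes, and DESeq2 size factors 716 and 1291. Without genes that share exons 524 and 992 remained, without muscle, adipocyte and red cell genes 695 and 1281, and without the sex-linked genes 691 and 1314. The 11 lists above the random range stayed so under each alternative that gave a value, and the natural killer and B cell lists had too few genes for one at 5 CPM. These 11 include the sex-linked list (4 members higher, 1 lower), whose median depends on how many Y-linked genes were listed. Of the 16 below, the NF-kB list lay within it against unmatched random lists (percentile 3.23) and, with the immediate early, mitochondrial and glycolytic lists (percentiles 4.03, 16.8, 8.78 and 4.37), without genes that share exons. The type 2 list did so with no filter (8.49) and the acute phase list at 5 CPM (20.3). The 10 highest and 10 lowest genes kept 14 of 20 members with a pseudocount of 0.1 and 11 without genes that share exons. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out. Depth limits the lymphocyte genes, many of which had under 20 counts in the WT library.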

Other observations

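The follicle stem cell, iron and NRF2, inflammasome, fatty acid synthesis, clock and imprinted gene lists and the tests of explanations were chosen after the data had been seen. In the library labelled KAT8 cKO, 7 of 16 stem and progenitor markers of the upper hair follicle and bulge were at least 2-fold higher and none lower (median log2 ratio 0.69). Of these 7, Krt15, Lhx2, Sox9 and Postn had already been named as higher from other lists, so the list is not separate evidence. Lgr6 went from 6.51 to 55.8 CPM, Lgr5 from 0.955 to 9.16 CPM, Gli1 from 2.86 to 9.51 CPM and Krt15 from 47.5 to 322 CPM, while Cd34, Plet1 and Lrig1 had log2 ratios of -0.22, 0.05 and 0.41. Iron handling and NRF2 target genes had 5 of 13 lower and none higher (median -0.78, percentile 0.02). The ferritin genes Fth1 and Ftl1 went from 7451 to 2344 CPM and from 1103 to 367 CPM, and the haem oxygenase gene Hmox1 from 315 to 128 CPM. Inflammasome and pyroptosis genes had 5 of 14 lower and 1 higher (median -0.65, percentile 0.03). Nlrp3, Casp1 and Il18 had log2 ratios of -1.85, -1.53 and -1.59, and Gsdma3 went the other way at 1.95. Myeloid cells express many of these iron and inflammasome genes, and the neutrophil and monocyte lists were lower in the same library (medians -2.05 and -0.85).

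Fatty acid synthesis genes as a list did not stand apart (4 higher and 4 lower of 21, median -0.04, percentile 46.8). Members went far in both directions. Scd1, Elovl4 and Elovl6 went from 1456 to 5012, from 517 to 2170 and from 62.6 to 1089 CPM, whereas Thrsp, Mlxipl and Agpat2 had log2 ratios of -5.14, -1.80 and -1.59. The adipocyte list was lower (median -2.58) and the sebaceous list higher (2.35) in the same library. Clock genes were at percentile 65.1 (median 0.09), with Per1, Per2 and Dbp at 0.03, -0.67 and 0.29. Imprinted genes were at percentile 25.2 (median -0.09), although H19 went from 84.5 to 6.68 CPM and Dlk1 from 1.74 to 9.99 CPM.

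The neutrophil and psoriatic keratinocyte lists were lower in the library labelled KAT8 cKO, with medians of -2.05 and -1.30, as were the muscle, adipocyte and immediate early lists, with -2.07, -2.58 and -0.80 (the last -0.16 without genes that share exons). The late epidermal differentiation list was lower too (-1.36) and the basal list higher (0.44). Among keratinocyte genes the lower values were thus not particular to the psoriatic list. Blood left in the specimen labelled WT is argued against as the source of the neutrophil transcripts, since haemoglobin genes, which dominate blood RNA, totalled 162 CPM there and the neutrophil list 5858 CPM, a ratio of 0.0277. A lower share of leukocyte transcripts of every kind in the other specimen is argued against by the T cell and dendritic medians, of which the lower was 0.69. The monocyte median was -0.85, and the B cell and mast cell medians (-0.20 and -0.14) lay within the random range. These medians had been seen before the comparison was chosen, and CPM are shares, so numbers of leukocytes stay open. Neither comparison bears on the psoriatic keratinocyte list. The genotype, the sex of the animals (Xist log2 ratio -9.51), another tissue make-up or handling of the specimens, or variation between animals may lie behind the difference. Sex and genotype cannot be told apart, because no library of the same sex was analysed in both genotypes.

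The sebaceous and cholesterol synthesis lists stood above the random range in the library labelled KAT8 cKO, with medians of 2.35 and 0.56. At least 2-fold higher were 10 of 14 sebaceous and 7 of 18 cholesterol synthesis genes. The cartilage and Schwann cell lists were higher too (1.26 and 1.04) and the muscle and adipocyte lists lower (-2.07 and -2.58), so the specimens differed in tissue markers, and another make-up of the specimen stays open. A larger amount of epidermis of every kind is argued against, since the sebaceous median lay 1.92 log2 units above the higher of the basal and differentiation medians. A candidate explanation is the sex of the animals (Eif2s3y log2 ratio 5.88), as sebaceous glands respond to androgens, and it cannot be told apart from the genotype for want of matched sexes. Whether there were more glands or more transcripts per gland was not tested.

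Kat8 was 1.27-fold higher in the library labelled KAT8 cKO. An exchange of the labels, another tissue make-up of the specimens, reads shared with Prss8 or variation between animals may account for this. A knockout restricted to few cells of the skin, or exons outside a deleted part, could leave the gene not lower but not raise it. These cannot be told apart from the gene's total, since the cells targeted and the deleted exons are not given in the sources used here and the ratio is close to 1. If the labels were exchanged, each direction given above would be that of the other genotype.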
